A study of Mus musculus with 4 samples.

How the data were processed

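RNA was measured in forelimbs dissected from C57BL/6 mouse embryos at stage E11.5. Per the labels' protocols, limbs of the same genotype were pooled, total RNA was extracted with TRIzol, and biotin-labelled cRNA was made by the standard Affymetrix procedure. Per the labels, the embryos came from different pregnancies, and each genotype, wild type and Shox2 knockout, had 2 arrays. Groups and the numbers 48 and 50 were taken from the sample titles. The labels do not say that a number marks a pregnancy, a day or a batch, so samples were treated as sharing only a number. Each array is a separate pool, and p-values of single genes measure only the spread between these pools. Those of the set test camera, described below, compare list members with other genes. At its preset correlation it treats genes as almost independent, so a pool difference shared by co-regulated genes could also pass.

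The authors deposited 1 table with a value per probe set and array, and its values were read as log2 expression because they lie between 5.04 and 14.1 in every column. In the deposited log2 table the sorted values of 3 arrays were identical and those of knockout array 48 lay within 0.00171 of them, which shows quantile normalization across the 4 arrays. In that array 31.4% of the values lay on the grid of even steps that held 100% of the values of the others, so its deposited values were rounded or interpolated in another way. The array platform, the background correction and the summarisation of probes were not given in the sources used here. The deposited values were used without further normalization. Quantile normalization makes all arrays equally bright, so a shift shared by most genes would not be seen.

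The table had 25206 probe sets. An annotation of the probe sets gave 1 gene name to 23185 of them, several names to 0 and none to 2021, which are unnamed here. Symbols were looked up again through the Entrez Gene identifier and 0 changed. No gene had more than 1 probe set. Named genes whose mean over the 4 arrays was at or above percentile 40 of all probe sets, a log2 level of 5.60, were tested. This left 14095 genes and set aside 9090 as too dim. Shox2 and all other genes were compared between the genotypes with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) on the log2 values, two-sided, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are those of the moderated fit, and standard deviations are over the 2 arrays of a group. There is no read depth for arrays: the number of arrays limits the precision, and values near the bottom of the range are compressed. Array numbers were also compared with each other, and so was the remaining split of the arrays into pairs, in the same way. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

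The gene lists, the rule for named genes, the test and all alternatives but 1 were fixed before the data were examined. By that rule Shox2 came first, followed by genes past the adjusted threshold with non-overlapping genotypes, up to 14 in each direction. As fewer than 20 passed, genes were added in order of unadjusted p, at least 1.5-fold different and with non-overlapping genotypes, until 24 were named. There were 28 lists, covering limb patterning, signalling pathways, skeletal tissues, other cell types of a dissected limb, cell states, sex-linked genes and the chromosomal neighbours of Shox2. From each list up to 4 members past the test over all genes were named, and where fewer than 2 passed, the 2 to 4 members with the smallest unadjusted p. Further Hox genes past the test over their list, Bmp4, Hba-x, Vegfa and Pitx1 were named after their values were seen. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists, and member genes were also counted after adjustment over the list alone. That adjustment is not corrected for the number of lists. Members said to rise or fall over a list alone can therefore include more false ones than the threshold states. Of the 28 lists, 10 passed camera, 8 higher and 2 lower in the knockout. With an estimated correlation 0 passed, the smallest adjusted p being 0.514, and with fry, which asks whether a list's genes move on balance in the same direction, 2 passed. The design leaves 2 residual degrees of freedom, from which the correlation must be estimated.

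The alternatives were no filter and a filter at percentile 60, quantile normalization or median centring on top of the deposited values, an intensity trend or a robust fit in eBayes, the unnamed probe sets tested too, a block for the array number, each array left out in turn, other thresholds and other set tests. Leaving out X- and Y-linked genes was added after the Y-linked genes were seen. With an array left out, the lone array of a group was assumed to vary like the other group.

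The procedure was tested on simulated data of the same size, in 10 runs with 200 of 14095 genes changed. It recovered 59.4% of genes changed by 0.6 on the log2 scale, 95.6% at 1, 99.6% at 2 and 100% at 4, with 4.29% false genes among the calls, and without any change it called 0 genes. A list of 20 genes shifted by 0.3 passed camera at the preset correlation in 10 of 10 runs and at an estimated correlation in 0 of 10, and of 270 lists without a shift 0 passed. The simulated noise was independent between genes and held no difference between array numbers. Having 200 changed genes also makes the adjusted threshold easier to reach. These rates may therefore not carry over to the real arrays.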

Results

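Gene expression was compared between forelimbs of wild-type mouse embryos and of embryos lacking Shox2, all dissected at stage E11.5 of gestation and of the C57BL/6 strain. Shox2 encodes a homeodomain transcription factor that is needed for growth of the proximal limb skeleton, and the comparison asks which transcripts differ in the forelimb when it is lost. Each array measured RNA pooled from the forelimbs of several embryos of the same genotype. There were 2 arrays per genotype, numbered 48 and 50 in their titles. Every array gave a log2 expression value for 25206 probe sets, with values between 5.04 and 14.1 and a median of 5.89. Pearson's r between arrays, taken across probe sets, lay between 0.995 and 0.997; probe sets are not independent replicates, so these coefficients only describe the arrays. In all, 14095 named genes were bright enough to be tested, and the number of arrays (n = 2 pools per genotype) limited the precision of every difference.

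Shox2 itself (Entrez Gene 20429) was measured at lower levels in both knockout pools than in both wild-type pools. Its log2 level averaged 9.23 ± 0.49 in the knockout and 10.47 ± 0.14 in the wild type (SD, n = 2 pools per genotype), a log2 difference of -1.24 ± 0.21 (SE) or a 2.36-fold lower level. Across the 14095 genes this was the most negative difference, and it ranked at place 31 by unadjusted p. With limma it did not pass the threshold after adjustment over all genes (adjusted p = 0.322). The knockout arrays read 9.58 (number 48) and 8.88 (number 50), and the wild-type arrays read 10.57 and 10.37. The mean knockout level still stood at percentile 83.9 of all probe sets, against percentile 93.7 in the wild type. Where the Shox2 probes lie relative to the deleted part of the gene is not given in the sources used here. Neither the drop nor the remaining signal can therefore be assigned to the deleted part. Without knockout array 48 the difference was -1.59 and passed (limma, adjusted p = 0.0349), and without knockout array 50 it was -0.89 and did not (limma, adjusted p = 0.456).

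The genes that rose in the knockout were the Y-linked genes Eif2s3y, Uty and Kdm5d, which encode a translation initiation factor subunit, a member of a histone demethylase family and a histone demethylase. Eif2s3y had a log2 level of 9.60 ± 0.063 in the knockout and 5.32 ± 0.079 in the wild type (SD, n = 2 pools per genotype), a difference of 4.29 ± 0.086 (SE; limma, adjusted p = 1.30e-05). Uty differed by 4.15 ± 0.11 (limma, adjusted p = 4.95e-05) and Kdm5d by 3.48 ± 0.11 (limma, adjusted p = 0.000106). Their wild-type means stood at percentiles 18.9, 4.47 and 33.1 of all probe sets, close to the bottom of the array's range, so the size of these differences depends on that floor. Xist, the RNA that silences an X chromosome in female cells, had a log2 level of 11.84 ± 0.23 in the knockout and 12.86 ± 0.033 in the wild type, and its difference of -1.01 ± 0.12 (SE) did not pass over all genes (limma, adjusted p = 0.217). It did pass with an intensity trend in the variance model (limma, adjusted p = 0.0121). As a list fixed for the sex composition of the pools, these 4 genes passed the set test (limma's camera, adjusted p = 7.23e-07), with adjusted p = 0.514 under an estimated correlation, and all 4 passed adjusted over the list alone. Both knockout pools thus carried Y-linked signal that stood near the bottom of the range in both wild-type pools, and every difference between the genotypes reported here was measured between pools that also differed in this respect.

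**Figure D1:**
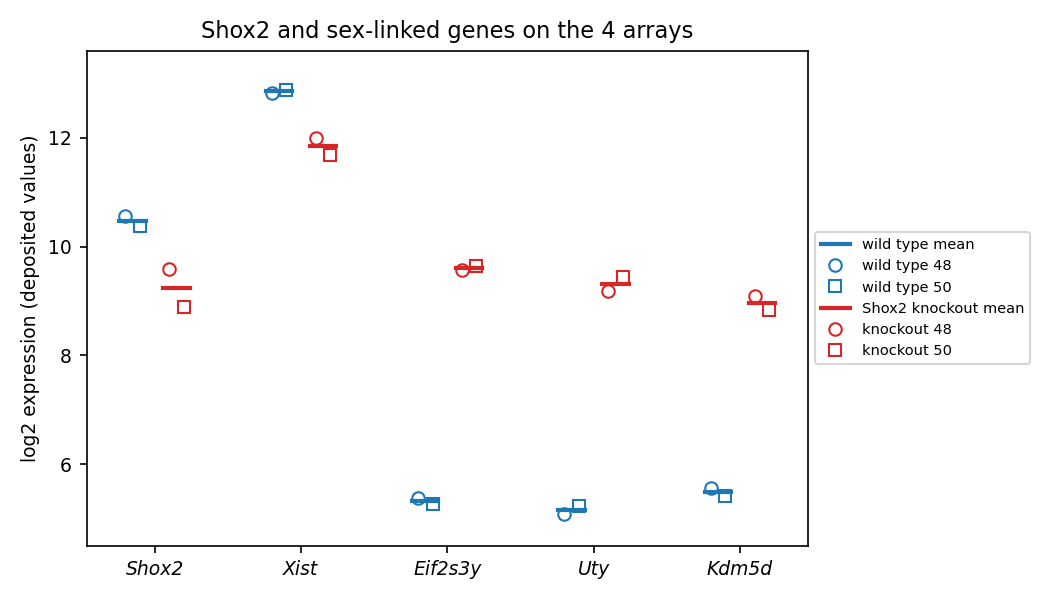
Log2 expression (vertical axis, deposited values) of Shox2, Xist and the 3 Y-linked genes on the 4 arrays; circles are arrays numbered 48, squares arrays numbered 50, horizontal lines group means, blue wild type and red knockout. Shox2 averaged 10.47 in the wild type and 9.23 in the knockout, and Eif2s3y averaged 5.32 and 9.60.

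Over all 14095 genes, limma called 3 genes higher and 0 lower in the knockout at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 731 higher and 705 lower genes, 1436 in all, where chance alone would give about 704.75. A change of at least 1.5-fold was measured for 57 genes, 36 higher and 21 lower. The genotypes did not overlap in 5918 genes, 42.0% of those tested, while chance gives 33.3% for 2 against 2 arrays. Leaving out any of the 4 arrays in turn gave 1 gene called lower, a different gene each time: Shox2 without knockout array 48, Lypd10 without wild-type array 48, Atp6v1g1 without knockout array 50 and Rxfp2 without wild-type array 50. The 3 Y-linked genes stayed called higher in all 4 runs, and 3 of the runs added a higher gene: Hoxd13 without knockout array 48, 5830417I10Rik without wild-type array 48 and Mir1195 without wild-type array 50. Lypd10, Atp6v1g1, 5830417I10Rik and Mir1195 are named here after their values were seen. Without the filter on dim genes, Kdm5d missed the threshold (limma, adjusted p = 0.0547). Splitting the same arrays by their title number called 0 genes with limma (smallest adjusted p = 0.0772). In that split 968 genes had an unadjusted p under 0.05 and 52 were at least 1.5-fold different. The remaining split called 0, with 114 and 9. The largest absolute log2 difference was 3.25 in the split by number and 0.93 in the remaining split, against 4.29 between the genotypes.

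Because few genes passed, 20 more were named in order of their unadjusted p among those at least 1.5-fold different with non-overlapping genotypes. None of these passed the test over all genes, and apart from Zfp935 (adjusted p = 0.163) and Xist each had an adjusted p of 0.322 in limma. On the lower side stood Rdh10, an enzyme of retinoic acid synthesis, at a log2 difference of -0.60 ± 0.082 (SE, n = 2 pools per genotype), and Wif1, a secreted WNT inhibitor, at -0.63 ± 0.11. Rxfp2, a receptor of the relaxin family, had a log2 level of 7.80 ± 0.032 in the knockout and 8.79 ± 0.35 in the wild type (SD), and without wild-type array 50 its difference of -1.25 passed (limma, adjusted p = 0.0404). The other lower genes were the zinc finger gene Zfp935 (-0.79), the histone gene H3f3a (-0.81), Lrrc32 (-0.63), the carbonic anhydrase gene Car2 (-0.62) and the protocadherin gene Pcdhb21 (-0.60). Pcdhb21 averaged 5.48 in the knockout, at percentile 32.8 of all probe sets, so the size of its difference depends on the floor of the array. On the higher side, Rspo3, which encodes a secreted enhancer of WNT signalling, differed by 0.71 ± 0.10, Gdf5, a joint and digit morphogen of the BMP family, by 0.76 ± 0.13, and Sall1, a zinc finger transcription factor of distal mesenchyme, by 0.90 ± 0.17. Kera, encoding the matrix proteoglycan keratocan, differed by 0.88 ± 0.15. Also higher were the steroid dehydrogenase gene Hsd3b6 (0.93), Cbln2 (0.80), the cadherin gene Cdh10 (0.72) and the prokineticin receptor gene Prokr2 (0.66). The antigen receptor segments Trav8d-1 (0.81) and Igkv4-58 (0.59) and the family member Btbd35f12 (0.65) completed the higher side. These 3, H3f3a and Pcdhb21 have closely related copies elsewhere in the genome, so their probe sets are uncertain.

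The list of limb Hox genes moved up in the knockout pools, though not all its members did. Of 15 limb Hox genes tested, 10 had higher and 5 lower values, with a median log2 difference of 0.32, and the list rose in the set test (limma's camera, adjusted p = 0.00334). With an estimated correlation it did not pass (adjusted p = 0.514). Hoxd13 and Hoxa13, which specify the hand plate, differed by 1.77 ± 0.40 and 0.98 ± 0.28 (log2, SE, n = 2 pools per genotype). Hoxd13 measured 8.58 ± 0.95 in the knockout and 6.81 ± 0.33 in the wild type (SD). Within each genotype both genes were also higher on number 50 than on number 48. Hoxd13 read 7.91 (48) and 9.25 (50) in the knockout and 6.58 and 7.04 in the wild type. Hoxa13 read 7.02 and 7.81 in the knockout and 6.15 and 6.72 in the wild type. Smaller differences between the genotypes were measured for Hoxd12 (0.57), Hoxd11 (0.45), Hoxd10 (0.44), Hoxa10 (0.37), Hoxa11 (0.33) and Hoxa9 (0.32). Adjusted over the list alone, these 8 genes rose and Hoxb6 fell (-0.27), whereas 0 passed in limma over all genes and 9 had an unadjusted p under 0.05. Without knockout array 48, Hoxd13 differed by 2.44 and passed over all genes (limma, adjusted p = 0.0349). Without knockout array 50 the differences were 1.10 for Hoxd13 (adjusted p = 0.515) and 0.59 for Hoxa13 (adjusted p = 0.680). Genes of the distal mesenchyme and the apical ridge moved the same way: 15 of 18 tested genes had higher values, the median difference was 0.15, and the list rose (limma's camera, adjusted p = 5.83e-05; adjusted p = 0.514 with an estimated correlation). Sall1, the LIM homeobox genes Lhx2 (0.45 ± 0.085) and Lmx1b (0.37 ± 0.081) rose adjusted over that list alone, and Msx1, a homeobox gene of undifferentiated mesenchyme, differed by 0.51 ± 0.16 without passing. Between the arrays numbered 48 the list medians were 0.35 for Hox and 0.23 for distal genes, and between those numbered 50 they were 0.28 and 0.15. Both lists passed camera with any array left out. The knockout pools with these higher values were also those with Y-linked signal, and in them the lists for erythroid cells and endothelium had lower medians (-0.14 and -0.098) and those for muscle, neurons and hypoxia higher ones (0.071, 0.10 and 0.16).

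**Figure D2:**
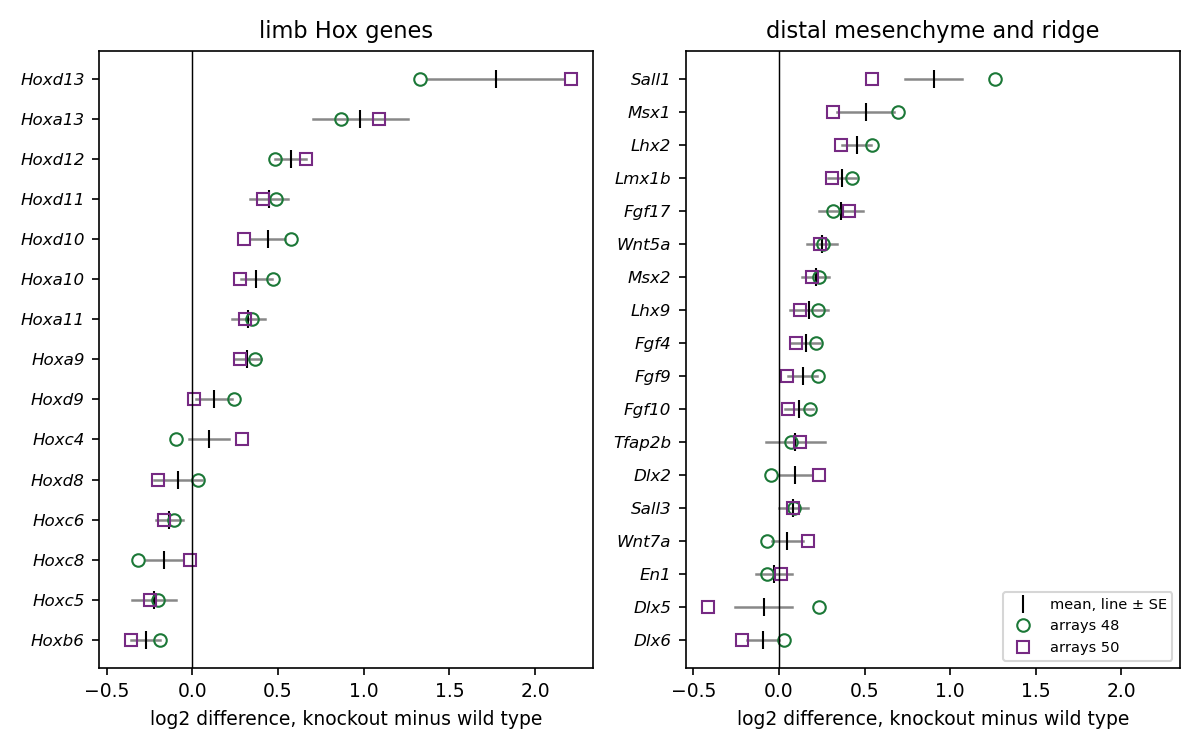
Log2 difference, knockout minus wild type (horizontal axis), of each tested limb Hox gene (left) and distal mesenchyme or ridge gene (right); black ticks are means of 2 arrays per genotype with lines of ± SE, green circles the difference between arrays numbered 48 and purple squares that between arrays numbered 50. Hoxd13 had the largest mean difference, 1.77, and 10 of 15 Hox and 15 of 18 distal genes lay above 0.

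Other patterning genes of the limb gave a mixed picture. In the proximal list, made of genes such as the Meis and Pbx homeobox genes of the upper limb, 8 of 13 genes had lower values, with a median of -0.075, and the list did not pass (limma's camera, adjusted p = 0.200). Tbx18, a T-box gene, fell adjusted over that list alone (-0.47 ± 0.10), and the homeobox gene Irx5 differed by 0.23 ± 0.083 without passing. Without wild-type array 50 the proximal list passed with a median of -0.18 (adjusted p = 0.0343), and without wild-type array 48 its median was 0.031. The hedgehog and anteroposterior list did not shift (17 genes, median 0.014, adjusted p = 0.783), although Tbx2 (0.48 ± 0.086) and Hand2 (0.41 ± 0.10), transcription factors of the posterior limb, rose adjusted over it. Shh, the signal of the posterior limb margin, differed by 0.18 ± 0.089 without passing. The short hindlimb list rose with 3 of 4 genes higher and a median of 0.26 (limma's camera, adjusted p = 0.0231; adjusted p = 0.514 with an estimated correlation). Its higher members adjusted over the list alone were Tbx4, a T-box gene of the hindlimb (0.54 ± 0.10), and Pcdh17 (0.44 ± 0.12, and 0.29 without knockout array 48), while Isl1 stood at -0.011; Pitx1 was too dim to be tested. The hindlimb median was 0.38 between the arrays numbered 48 and 0.17 between those numbered 50. Without the filter on dim genes the hindlimb list did not pass (median 0.028; limma's camera, adjusted p = 0.295). The pools that differed in it also differed in Y-linked signal. By their medians over all 4 arrays, the erythroid and endothelial lists were lower in the knockout and the muscle and neuronal lists higher. The muscle median was 0.17 between the arrays numbered 48 but -0.016 between those numbered 50. Among 13 candidate targets of Shox2 or its human relative SHOX, taken from background knowledge, 5 had higher and 8 lower values. This list did not pass (adjusted p = 0.941), with a median of -0.031 and a mean of 0.035, so that its median and its test differed in sign. Tbx4 rose adjusted over this list too, Ihh, a signal of growing cartilage, differed by 0.48 ± 0.14, and Bmp4 by -0.086 ± 0.12.

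Among signalling pathways, no list passed with all 4 arrays and the filter at percentile 40. Retinoic acid genes had a median of 0.016 over 14 genes (limma's camera, adjusted p = 0.941), but 4 of them passed adjusted over the list alone, in opposite directions. Rdh10 and Dhrs3 (-0.34 ± 0.099), enzymes of retinoid synthesis and turnover, fell over this list, while Cyp26b1, which degrades retinoic acid (0.56 ± 0.12), and the receptor gene Rarg (0.27 ± 0.083) rose. In limma 0 retinoic acid genes passed over all genes. In the WNT list (26 genes, median 0.043, adjusted p = 0.577), Rspo3 rose and Wif1 fell adjusted over the list alone. Without knockout array 50 that list passed (median 0.057, adjusted p = 0.0428), and without knockout array 48 its median was -0.032. The BMP and GDF list had a median of 0.056 over 24 genes (adjusted p = 0.107), with Gdf5 and the BMP antagonist gene Smoc1 (0.41 ± 0.085) up over the list alone. It passed under the stricter filter on dim genes (median 0.10, adjusted p = 0.0440), and with each array left out its median ran from 0.037 to 0.079. FGF signalling genes had a median of 0.0053 and a mean of -0.020 over 18 genes (adjusted p = 0.941), the test pointing down against the sign of the median. In that list 0 genes passed in limma and 1 had an unadjusted p under 0.05, the FGF feedback inhibitor gene Spry1, at -0.30 ± 0.10; the FGF target gene Dusp6 differed by -0.18 ± 0.085.

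Cartilage genes did not move together at this stage. Of 29 chondrogenesis genes, 14 had higher and 15 lower values, with a median of -0.0017, a mean of 0.0087 and a test pointing up (limma's camera, adjusted p = 0.955). In limma 0 of them passed and 5 had an unadjusted p under 0.05, among them the collagen gene Col9a2 (0.39 ± 0.092), the transcriptional repressor gene Nkx3-2 (0.43 ± 0.12), Ihh, and the cartilage matrix gene Matn1 (-0.29 ± 0.088). Osteogenesis and hypertrophy genes had a median of -0.040 over 12 genes (adjusted p = 0.955), with 0 genes past limma and 0 at an unadjusted p under 0.05; the bone transcription factor gene Sp7 differed by -0.26 ± 0.12 and Twist1 by 0.16 ± 0.079. The joint and interzone list rose with 10 of 14 genes higher and a median of 0.093 (limma's camera, adjusted p = 0.0106; adjusted p = 0.514 with an estimated correlation). Adjusted over the list alone, Gdf5, the transcription factor gene Ebf1 (0.45 ± 0.090) and Osr2, a zinc finger gene of joints (0.90 ± 0.19), rose. The joint median was 0.13 between the arrays numbered 48 and 0.097 between those numbered 50. The joint call was lost without knockout array 48 (median 0.077) and without wild-type array 50 (median 0.11). The same pools differed in Y-linked signal. By their medians over all 4 arrays, the erythroid and endothelial lists were lower in the knockout and the muscle and neuronal lists higher. The muscle list was not higher between the arrays numbered 50 (median -0.016). Tendon and connective tissue genes did not pass as a list (27 genes, median 0.034, mean 0.0026, test pointing down, adjusted p = 0.955). Over that list alone Kera and the tendon regulator gene Mkx (0.47 ± 0.11) rose and the matrix gene Postn (-0.37 ± 0.080) fell.

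Markers of other cell types held by a dissected forelimb moved by small amounts. Erythroid genes fell as a list, with 12 of 15 lower and a median of -0.14 (limma's camera, adjusted p = 0.00680; adjusted p = 0.859 with an estimated correlation). The heme synthesis gene Alas2 differed by -0.57 ± 0.17 and the red cell anion exchanger gene Slc4a1 by -0.34 ± 0.099, and Hemgn, a gene of erythroid progenitors, by -0.31 ± 0.084, whereas the embryonic globin gene Hba-x stood at 0.14. The erythroid median was -0.050 between the arrays numbered 48 and -0.19 between those numbered 50. The erythroid call was lost without wild-type array 50 (median -0.039, adjusted p = 0.432) and under the stricter filter (adjusted p = 0.211). Endothelial genes fell with 17 of 23 lower and a median of -0.098 (limma's camera, adjusted p = 0.0106; adjusted p = 0.535 with an estimated correlation). The VEGF receptor gene Kdr differed by -0.28 ± 0.083 and the angiopoietin receptor gene Tek by -0.27 ± 0.087, and the call was lost without knockout array 48 (median -0.061, adjusted p = 0.102). Skeletal muscle genes rose with 20 of 29 higher and a median of 0.071 (limma's camera, adjusted p = 0.0338; adjusted p = 0.859 with an estimated correlation). Acta1, encoding skeletal actin, differed by 0.50 ± 0.11 and the troponin gene Tnni1 by 0.34 ± 0.077. Between the arrays numbered 48 the muscle median was 0.17, and between those numbered 50 it was -0.016. The muscle call was lost without knockout array 48 (adjusted p = 0.0824) and without the filter (adjusted p = 0.238), and without wild-type array 48 the median was -0.038. Neuron and axon genes rose with 11 of 13 higher and a median of 0.10 (limma's camera, adjusted p = 0.0486; adjusted p = 0.859 with an estimated correlation). Stmn3, a neuronal stathmin gene, differed by 0.36 ± 0.15 and Mab21l2 by 0.28 ± 0.12, and the neuronal call was lost without wild-type array 48 (adjusted p = 0.253), without wild-type array 50 (adjusted p = 0.0547) and without knockout array 50, where the median was -0.0015. It was also lost under the stricter filter (adjusted p = 0.0540), with the unnamed probe sets added (adjusted p = 0.0527) and with X- and Y-linked genes left out (adjusted p = 0.0728), a setting chosen after the data were seen. In limma 0 members of these 4 lists passed over all genes, while 4 erythroid, 4 endothelial, 4 muscle and 1 neuronal gene had an unadjusted p under 0.05. Between the arrays numbered 48 the endothelial median was -0.13 and the neuronal one 0.077, against -0.072 and 0.13 between those numbered 50. All 4 shifts were measured between pools that also differed in Y-linked signal.

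The remaining cell type lists did not pass camera with all 4 arrays and the filter at percentile 40, and 0 of their members passed in limma over all genes. Surface ectoderm genes had a median of 0.055 over 21 genes (adjusted p = 0.630), with 4 at an unadjusted p under 0.05, and passed under the stricter filter on dim genes (median 0.10, adjusted p = 0.0380). Within that list the epithelial transcription factor gene Bnc1 differed by -0.29 ± 0.087, and the keratin genes Krt8 (0.30 ± 0.10) and Krt18 (-0.29 ± 0.096) differed in opposite directions. Schwann and neural crest genes had a median of -0.0027 and a mean of 0.021 over 10 genes, with a test pointing up (adjusted p = 0.733) and 2 genes at an unadjusted p under 0.05, Egfl8 (0.36 ± 0.092) and the receptor kinase gene Kit (0.21 ± 0.084). Macrophage genes had a median of -0.0024 and a mean of 0.0075 over 15 genes, with a test pointing down (adjusted p = 0.955) and 2 at an unadjusted p under 0.05, the scavenger receptor gene Stab1 (-0.26 ± 0.096) and the coagulation factor gene F13a1 (-0.19 ± 0.077). Genes of heart, liver and trunk tissue had a median of -0.0088 over 8 genes (adjusted p = 0.941), with 2 at an unadjusted p under 0.05, the somite gene Meox1 (-0.63 ± 0.17) and the forkhead gene Foxc2 (0.26 ± 0.084).

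Genes of hypoxia and glycolysis rose as a list, with 19 of 22 higher and a median of 0.16 (limma's camera, adjusted p = 0.000157; adjusted p = 0.514 with an estimated correlation). The glycolysis genes Tpi1 and Pfkl differed by 0.34 ± 0.092 and 0.27 ± 0.094, Pfkfb3, whose product activates glycolysis, by 0.28 ± 0.089, and Vegfa, the angiogenic factor induced by hypoxia, by 0.16 ± 0.078. In limma 0 of these genes passed, over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05, all of them higher. With each array left out the median of the hypoxia list ran from 0.14 to 0.16. It was 0.17 between the arrays numbered 48 and 0.13 between those numbered 50. The pools that differed in this list also differed in Y-linked signal. By their medians over all 4 arrays, the erythroid and endothelial lists were lower in the knockout and the muscle and neuronal lists higher. The muscle list was not higher between the arrays numbered 50 (median -0.016). Cell cycle genes did not pass (29 genes, median -0.027, adjusted p = 0.618), with 0 genes past limma and 0 at an unadjusted p under 0.05; the replication gene Mcm3 differed by -0.18 ± 0.081 and the mitotic kinase gene Aurkb by 0.18 ± 0.095. Targets of p53 and apoptosis genes did not pass (15 genes, median -0.0044, adjusted p = 0.955), with 0 genes past limma and 2 at an unadjusted p under 0.05, Phlda3 (0.39 ± 0.094) and Aen (-0.25 ± 0.10). Immediate early and heat shock genes had 14 of 19 lower and a median of -0.064 (adjusted p = 0.200), with 0 genes past limma and 2 at an unadjusted p under 0.05, Ccn2 (-0.30 ± 0.11) and Nr4a1 (-0.28 ± 0.12). They passed without knockout array 48 (median -0.12, adjusted p = 0.0391) and without wild-type array 50 (median -0.086, adjusted p = 0.0343), and had a median of 0.0083 without knockout array 50. The 17 tested neighbours of Shox2 on its chromosome, listed to look for effects around the deletion, had a median of -0.051 (adjusted p = 0.577), with 0 genes past limma and 1 at an unadjusted p under 0.05, Rarres1, at -0.64 ± 0.22; Mfsd1 differed by -0.18 ± 0.099. With each array left out their median ran from -0.083 to -0.0034.

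**Figure D3:**
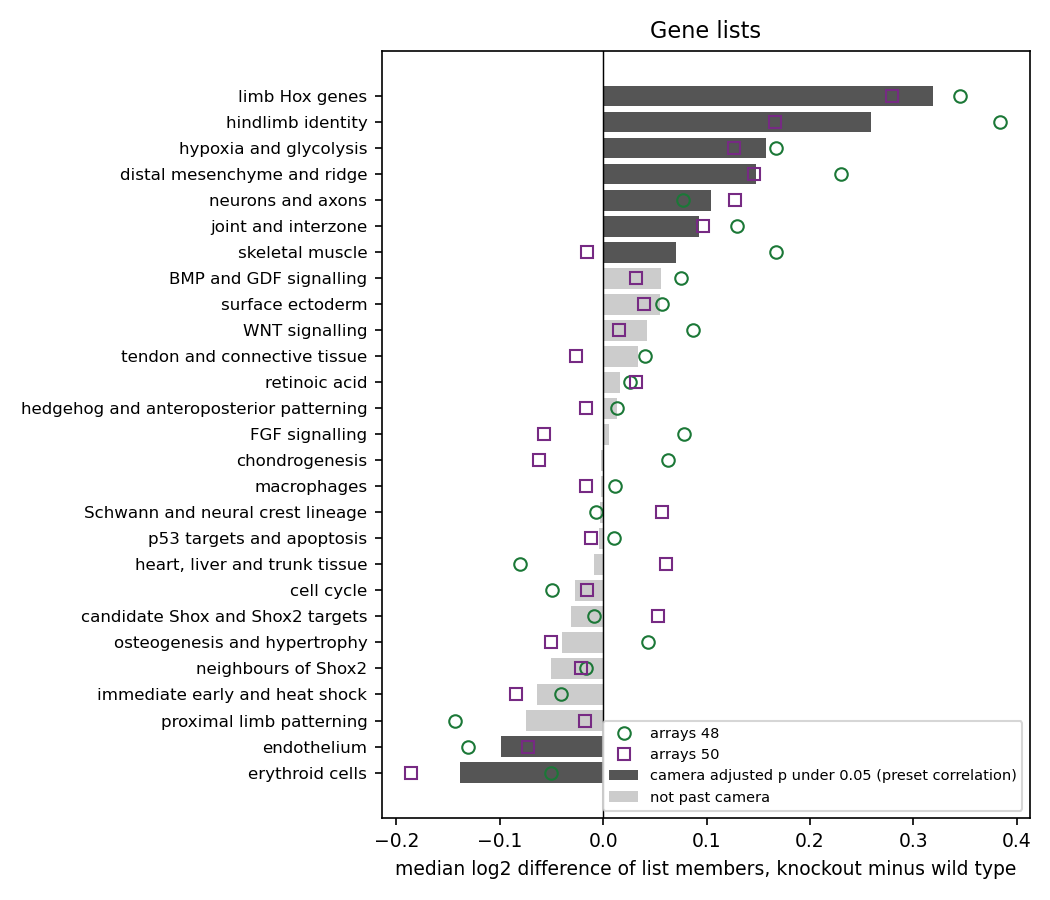
Median log2 difference, knockout minus wild type (horizontal axis), of the tested members of 27 gene lists, as bars from 0; green circles are medians between arrays numbered 48 and purple squares between arrays numbered 50, and dark bars passed limma's camera with a preset correlation. The sex-linked list, with a median of 3.81, is left off the plot; limb Hox genes had a median of 0.32 and erythroid genes one of -0.14.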

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

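When the 1029 unnamed probe sets above the brightness filter were added to the test, 1 of them passed: it stood apart because it lay outside the named genes that the comparisons used. Its log2 level averaged 7.82 in the knockout and 5.61 in the wild type, a difference of 2.21 ± 0.10 (SE, n = 2 pools per genotype; limma, adjusted p = 0.00115 over 15124 probe sets). The wild-type mean lay close to the brightness filter of 5.60, so the size of the difference depends on the floor of the array. The Y-linked genes had the same pattern, and the gene and chromosome of this probe set are not known here. Ddx3y, the remaining Y-linked gene of the sex-linked list, was not named on the array. A sex-linked origin of this difference therefore cannot be told apart from another origin.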

How the results depend on the processing

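The setting without X- and Y-linked genes was chosen after the data were seen; the others were planned. With quantile normalization on top, median centring or a robust fit, the counts of genes, Shox2, the 23 other named genes and the 28 lists kept their direction and their side of the threshold. Quantile normalization and median centring could hardly move the values, because the deposited ones were already quantile-normalized, so those settings test little. With an intensity trend 1 gene was lower, Xist. Without X- and Y-linked genes 0 genes were higher, as the 3 called genes are Y-linked. With a replicate block for the array number, limma called 203 genes higher and 179 lower, among them the 3 genes called without it and all 24 named genes, and Shox2 passed at -1.24 (adjusted p = 0.00167; its adjusted p under the other settings ran from 0.0349 to 0.549), while the same 10 lists passed. The correlation of the deviations of same-numbered arrays, across genes, was 0.388. In limma the split by number had 968 genes at an unadjusted p under 0.05 and the remaining split 114. Differences between the numbers thus add to the spread in the fit without a block. Camera with an estimated correlation passed 0 lists and fry 2, the sex-linked and the hypoxia lists. In simulated data of this size a list of 20 genes shifted by 0.3 passed with an estimated correlation in 0 of 10 runs, so a miss there does not tell a shifted list from an unshifted list; the cause for fry was not tested. The unnamed probe sets added 1 call and kept the 3. An offset before log2 did not apply to log2 values, nor a mean of several probe sets to genes with 1 each. A threshold of 0.1, or one of 0.05 with a 1.5-fold change, gave the same counts. Leaving out each array gave a Shox2 difference of -1.59 to -0.89. All 24 named genes kept their direction, but this was fixed in advance: each had non-overlapping genotypes, so leaving out 1 array could not reverse it. The cause of the changes with an array left out or with the trend was not tested, nor was what the array numbers stand for.

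Some lists changed the sign of their median, with causes not tested. Without the filter, where more genes are tested, chondrogenesis had 0.013 and heart, liver and trunk tissue 0.0073. Under the stricter filter, with fewer genes, hedgehog had -0.0088, retinoic acid -0.023 and Schwann genes 0.032. With each array left out, the medians ran from -0.036 to 0.023 for hedgehog, -0.031 to 0.036 for FGF, -0.032 to 0.073 for WNT and -0.042 to 0.082 for retinoic acid. They ran from -0.043 to 0.045 for candidate targets, -0.18 to 0.031 for proximal genes, -0.052 to 0.068 for chondrogenesis, -0.034 to 0.010 for osteogenesis and -0.097 to 0.0068 for tendon. They ran from -0.038 to 0.19 for muscle, -0.0015 to 0.15 for neurons, -0.022 to 0.078 for Schwann genes, -0.027 to 0.077 for macrophages and -0.022 to 0.10 for ectoderm. They ran from -0.040 to 0.031 for heart, liver and trunk tissue, -0.027 to 0.0098 for cell cycle, -0.022 to 0.010 for p53 and -0.12 to 0.0083 for immediate early genes. The limb Hox, distal, hypoxia, hindlimb and sex-linked lists passed camera in 4 of 4 such runs. Signal over background limits the Y-linked genes, whose wild-type levels lie near the floor.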

Other observations

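The protocadherin beta, X-linked and escape gene sets and the tests of explanations in this part were chosen after the results were seen; the limb Hox, distal, proximal, chondrogenesis, muscle and other gene lists and their set tests were not. Genes of the protocadherin beta cluster, which encode cell surface adhesion proteins, had mostly lower values in the knockout pools. Of 14 tested, 12 were lower and 2 higher, with a median log2 difference of -0.23 (-0.27 between the arrays numbered 48 and -0.22 between those numbered 50). In limma 0 of them passed over all genes, while 8 lower genes and 1 higher gene had an unadjusted p under 0.05. These genes are close paralogs, so their probe sets are uncertain, and the cluster was picked because of its values. Among all 483 tested X-linked genes the median difference was -0.0066 and 51.8% were lower, against -0.00098 and 50.4% for 13608 autosomal genes.

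The Y-linked genes Eif2s3y, Uty and Kdm5d were high in the knockout pools and near the bottom of the range in the wild-type pools. A candidate explanation is that the knockout pools held male embryos and the wild-type pools did not: 5 of 5 tested X-linked genes known to escape X inactivation were lower in the knockout (Kdm6a -0.38, Kdm5c -0.23, Ddx3x -0.21, Utp14a -0.18 and Pbdc1 -0.17), as was Xist (-1.01). In limma 0 of these 5 genes passed over all genes, and 3 of them, Kdm6a, Kdm5c and Ddx3x, had an unadjusted p under 0.05. A change of the Y-linked genes alone, through the loss of Shox2 itself, would leave Xist and the escape genes where they were. Their lower values, with Xist at -1.01 ± 0.12 (SE), argue against that as the cause of the whole pattern. Whether the loss of Shox2 added to the size of the differences was not tested. The levels do not tell how many male embryos a pool held. The knockout mean of Xist still stood at percentile 99.0 of all probe sets, so the knockout pools were not free of this RNA of female cells.

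The limb Hox and distal mesenchyme lists were higher in the knockout pools by camera at the preset correlation, but did not pass with an estimated one (adjusted p = 0.514 for each), and in the same pools the hypoxia, joint, hindlimb, muscle and neuronal lists were higher and the erythroid and endothelial lists were lower. A smaller share of proximal tissue stays open, as the proximal list did not pass (limma's camera, adjusted p = 0.200) yet had a median of -0.075. A later stage of the knockout embryos stays open too: the chondrogenesis list (adjusted p = 0.955), with members going both ways, decides nothing, and the muscle list passed (adjusted p = 0.0338) but not with an estimated correlation (adjusted p = 0.859), with medians of 0.17 between the arrays numbered 48 and -0.016 between those numbered 50. An effect of male embryos and an effect of the loss of Shox2 itself cannot be told apart, since 0 of 2 genotypes had pools that differed by over 1 log2 unit in Y-linked signal. The biological explanation, the loss of Shox2, therefore remains an untested hypothesis here.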
